A study of Mus musculus with 17 samples.

How the data were processed

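The series holds 17 libraries of RNA from CD1 mice in 6 groups. Of these, 7 were made from oocytes arrested at metaphase of the second meiotic division, about 10 oocytes per library, and 10 from the hippocampus of adult offspring aged 40 to 44 weeks, about 10 months. Each file holds one library's counts of reads per gene, as the authors deposited them, with no normalization. STAR, HTSeq and the mm10 genome build are named per the submitters' processing notes. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes could not be told apart from their neighbours.

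All files list the same 24491 gene symbols and 5 summary rows that name no gene. The summary rows were kept out of library sizes and tests. Relative to the total of each oocyte library, reads outside annotated genes made up 6.09% to 9.32%, reads without a unique position 10.0% to 15.9% and ambiguous reads 1.26% to 1.48%. In hippocampus the ranges were 11.7% to 16.0%, 5.09% to 8.01% and 1.66% to 1.92%. Reads assigned to genes came to 3912163 to 8334873 per oocyte library and 16434398 to 20220617 per hippocampus library. A floor of 3 counts corresponded to 0.360 to 0.767 CPM (counts scaled to the normalised library size) in oocytes and 0.148 to 0.183 CPM in hippocampus. Reads are not independent molecules here, so floors and counting intervals, given at the 95% level, cover counting error only.

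Groups, tests, gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Each tissue was fitted alone with all its 3 groups, so that they shared one estimate of spread. Genes were kept with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and groups were compared with the quasi-likelihood F-test of edgeR, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. This left 10083 genes in oocytes and 14877 in hippocampus. Printed levels are TMM-normalised CPM as mean ± SD, and printed errors of log2 fold changes are standard errors. A fold against a group at 0 was computed against 3 counts over that group, and a fold against 1 to 3 counts is given with its counting interval. The biological coefficient of variation was 49.5% in oocytes and 23.5% in hippocampus. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

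Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 34 lists, 15 of the 16 set for oocytes and 27 of the 29 set for hippocampus had at least 3 tested members. Symbols were matched to GENCODE mouse release M21 on GRCm38, the same assembly as mm10, and 15420 of 15907 genes tested in either tissue (96.9%) matched 1 gene there. That annotation may differ from the authors' one.

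The text names genes by a fixed rule. Among genes past the threshold with a mean of at least 2 log2 CPM, no overlap between the libraries of the groups and a standard symbol, it takes the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 pass in a direction, it takes the 5 of smallest unadjusted p and reports them as not passing. It adds up to 4 members of each list with the smallest unadjusted p, and Mtor, Rptor, Rps6kb1 and Eif4ebp1. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

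The same code was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 genes changed by known folds. For aged against young oocytes, 26% of genes changed 8-fold and 70% of those changed 16-fold were called, out of 9820 genes tested, with 3 false calls. Rapamycin against aged oocytes gave 34% and 68% over 9746 genes, with 2 false calls, and rapamycin against young oocytes 36% and 68% over 9831 genes, also with 2. For hippocampus, 2-fold changes were called in 52% of cases for aged against young (14760 genes), 48% for rapamycin against aged (14743 genes) and 38% for rapamycin against young (14735 genes). False calls there were 10 of 198, 14 of 199 and 8 of 189 calls in the same order.

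Alternatives were size factors by the relative log expression method, no low-count filter, a filter of 10 CPM, robust dispersions, only the 2 groups compared, a replicate block, DESeq2, thinning of all libraries to the smallest total, and leaving out each library in turn. A covariate for the level of the ribosomal protein list in hippocampus and leaving out Rn45s in oocytes were added after the data had been seen. No replicate pair shared values to within counting noise, with chi-square per degree of freedom of at least 12.1. The labels do not say that libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be partly technical. The hormone dose given before oocyte collection, 5 IU of each hormone in young mice and 10 IU in aged mice, went with age and cannot be separated from it. The design text speaks of 9 oocyte samples. The 7 given here were used, and the others were not analysed here.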

Results

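RNA sequencing was used to follow maternal age and rapamycin, an inhibitor of the mTOR kinase, in oocytes and in the brain of offspring. Oocytes came from young mice of 4 weeks (n = 2 libraries), aged mice of 48 weeks (n = 2) and aged mice given rapamycin at 2 mg/kg for 40 weeks from week 8 (n = 3). Hippocampus came from adult offspring of young mothers (n = 4), aged mothers (n = 3) and rapamycin-treated aged mothers (n = 3). Oocyte libraries held 3912163 to 8334873 counts and between 8688 and 10350 genes with at least 10 counts. Hippocampus libraries held 16434398 to 20220617 counts and between 14322 and 14741 such genes. In the text, rapamycin oocytes and rapamycin offspring stand for the groups of treated aged females.

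Oocyte libraries separated by group along the second principal component, which carried 23.1% of the variance, while the first (53.5%) set the library rapamycin 1 apart from the other 6. Across genes, log2 CPM of rapamycin 1 correlated with the other libraries at r = 0.728 to 0.786, against 0.867 to 0.975 among the rest. Transcripts of the oocyte growth factor Gdf9 stood at 302 CPM in that library and at 4928 to 9232 CPM in the other 6. The oocyte linker histone H1foo stood at 515 against 9744 to 13530 CPM, and the meiotic kinase Mos at 12.9 against 1072 to 1806 CPM. Tcl1, an abundant maternal transcript, was at 26460 CPM there and at most 10960 CPM elsewhere. The 45S ribosomal RNA gene Rn45s took 7.59% of its counts. These 5 genes were chosen after their values were seen. Hippocampus libraries did not separate by group along the first component (44.3%). Levels of the cytosolic ribosomal protein list differed within groups, from -0.55 to 0.70 log2 units in offspring of young mothers and from -0.91 to 0.67 in rapamycin offspring.

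**Figure D1:**
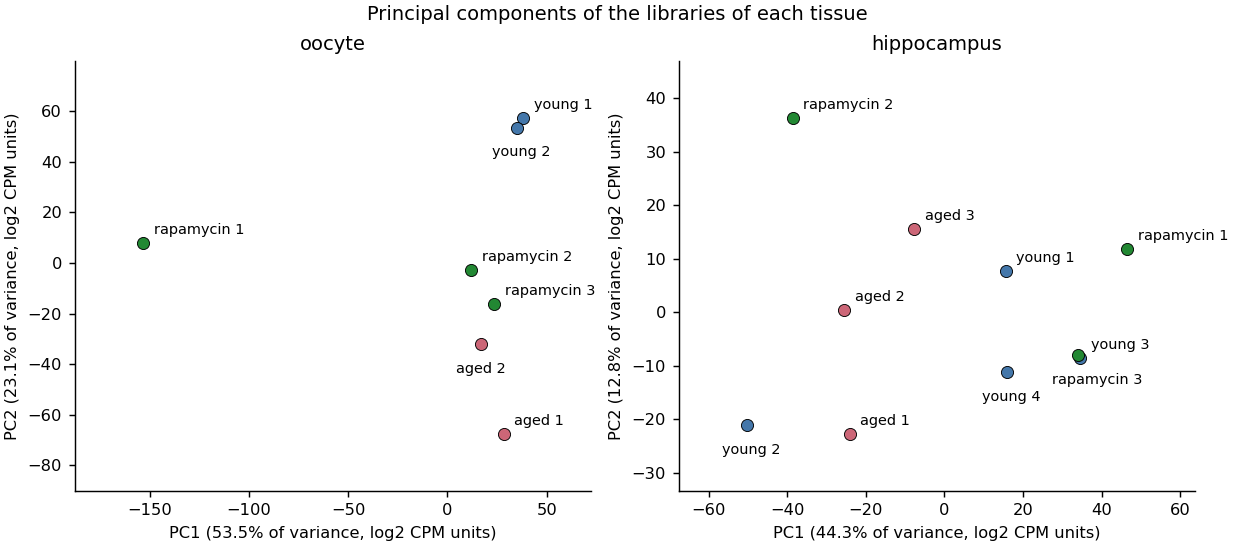
Principal components of log2 CPM for the 7 oocyte libraries (left) and the 10 hippocampus libraries (right), each point a library coloured by group, with PC1 on the horizontal and PC2 on the vertical axis. Oocyte rapamycin 1 lies alone at -153 on PC1.

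The first comparison asked how oocytes of aged mice differ from those of young mice. Pnpla3, a lipase acting on lipid droplets, rose from 1.58 ± 0.392 CPM (SD, n = 2) to 1465 ± 114 CPM (SD, n = 2), a log2 fold change of 9.81 ± 0.70 (edgeR adjusted p = 0.00721). Cdc5l, a splicing factor, rose by 5.79 ± 0.61 (adjusted p = 0.0181) and the mitochondrial fission regulator Mtfr2 by 4.54 ± 0.45 (adjusted p = 0.0163) on the log2 scale in the edgeR fit. In the other direction, Arid5b, a chromatin-binding transcription coactivator, fell by 6.63 ± 0.60 (adjusted p = 0.0138), from 454 ± 52.3 to 4.58 ± 2.67 CPM (SD, n = 2 each), in the same edgeR test. Dph6, an enzyme of diphthamide synthesis on elongation factor 2, fell by 5.22 ± 0.43 (edgeR adjusted p = 0.00983), and Tox3, a nuclear protein of the HMG-box family, fell by 7.03 ± 0.68 (edgeR adjusted p = 0.0163). Pnpla3 lies on chromosome 15 from 84167837 to 84187236 and Arid5b on chromosome 10 from 68092520 to 68278740 of GRCm38, both protein-coding.

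In all, edgeR called 27 of 10083 genes, 16 higher and 11 lower in aged oocytes, with 1162 at an unadjusted p under 0.05 (504 expected by chance). The homeodomain gene Pknox2 had 0 counts in both young libraries and was at least 60.3-fold higher in aged oocytes. The adhesion molecule Chl1 was 472-fold higher, with a counting interval of 84.0 to 18700. Ccdc85a was at 0 in both aged libraries, at least 60.9-fold lower, and the potassium channel Kcnk18 was 351-fold lower (62.7 to 13900). Other genes that rose were the extracellular peroxidase Pxdn (log2 fold change 7.99 ± 1.00), Agbl2 (4.96 ± 0.63), which trims glutamate from tubulin, Otogl (5.45 ± 0.79), Lrrc31 (3.97 ± 0.51) and the hypoxia-response factor Hif3a (3.82 ± 0.54). The clock gene paralogue Arntl2 fell by 5.81 ± 0.61, the aspartate aminotransferase Got1 fell by 4.51 ± 0.53, the collagen receptor Ddr2 fell by 4.83 ± 0.62 and the phosphoinositide phosphatase Inpp4a fell by 4.13 ± 0.59. Of the 75-base words in transcripts of Cdc5l, 72.2% occurred in no other gene, so part of its reads may not be assigned uniquely.

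Cytosolic ribosomal proteins lay lower in aged oocytes as a list, with 61 of 73 members below 0 and a median log2 fold change of -0.69 (camera adjusted p = 0.000131, adjusted p = 0.966 with an estimated correlation). Nuclear OXPHOS subunits, the respiratory chain proteins made in the cytosol, were below 0 in 62 of 70 members with a median of -0.67 (camera adjusted p = 0.000106, adjusted p = 0.479 with an estimated correlation). Without aged 1 the ribosomal median was -0.32 and the camera call ended. No list passed with fry, where the lowest adjusted p was 0.0649. In edgeR no member of either list passed over all genes or when adjusted over the list alone, while DESeq2 called 1 lower in each. Examples past the threshold in neither tool were Rps7 (-1.82 ± 0.52), Rpl35 (-2.04 ± 0.65), Cox7a2 (-1.01 ± 0.40) and Cycs (-1.05 ± 0.42). The other 13 lists had camera adjusted p from 0.495 to 0.951, and in edgeR none of their members passed over all genes or adjusted over the list alone. DESeq2 called 1 lower in each of DNA damage repair, DNA methylation and chromatin regulators, and oocyte identity. They were mTOR pathway components (median log2 fold change 0.11), translation initiation and elongation (-0.15), autophagy and lysosome (0.23), antioxidant defence (-0.52), DNA damage repair (0.03), DNA methylation and chromatin regulators (-0.13), heat shock and the unfolded protein response (-0.14) and oocyte identity (-0.02). The rest were imprinted genes (0.003), meiotic cohesin, spindle and checkpoint (0.14), cumulus and granulosa cells (-0.32), immune and blood cells (0.88), and deadenylation and cytoplasmic polyadenylation (0). Mtor (1.02 ± 0.71) and its target Eif4ebp1 (1.33 ± 0.67) did not pass in either tool. Mitochondrially encoded mRNAs have 0 members among the symbols of the files.

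The count of 27 depended on single libraries. It was 0 without young 1, young 2, aged 1 or aged 2, 13 without rapamycin 2, 10 without rapamycin 3, and 1168 of 10220 (641 higher, 527 lower) without rapamycin 1, which lowered the biological coefficient of variation from 49.5% to 28.1%. All 27 genes were among the 1168. The ribosomal protein genes Rps7 (-1.82) and Rpl35 (-2.05) were called without rapamycin 1, among 7 of 74 in that list, all lower. In other lists calls went both ways, with 3 higher and 4 lower in oocyte identity, 4 higher and 3 lower in DNA methylation and chromatin regulators, 6 higher and 1 lower in autophagy and lysosome, and 7 higher and 1 lower in deadenylation and cytoplasmic polyadenylation. The naive-pluripotency gene Dppa5a (-2.59), the maternal effect gene Dppa3 (-1.02), the DNA demethylase Tet1 (-3.12) and the chaperone Hspa5 (-1.80) were called there as well. The same 4 genes were called in the edgeR fit of only the 2 groups, which called 1177 genes, while DESeq2 called 240, Dppa5a and Tet1 among them.

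**Figure D2:**
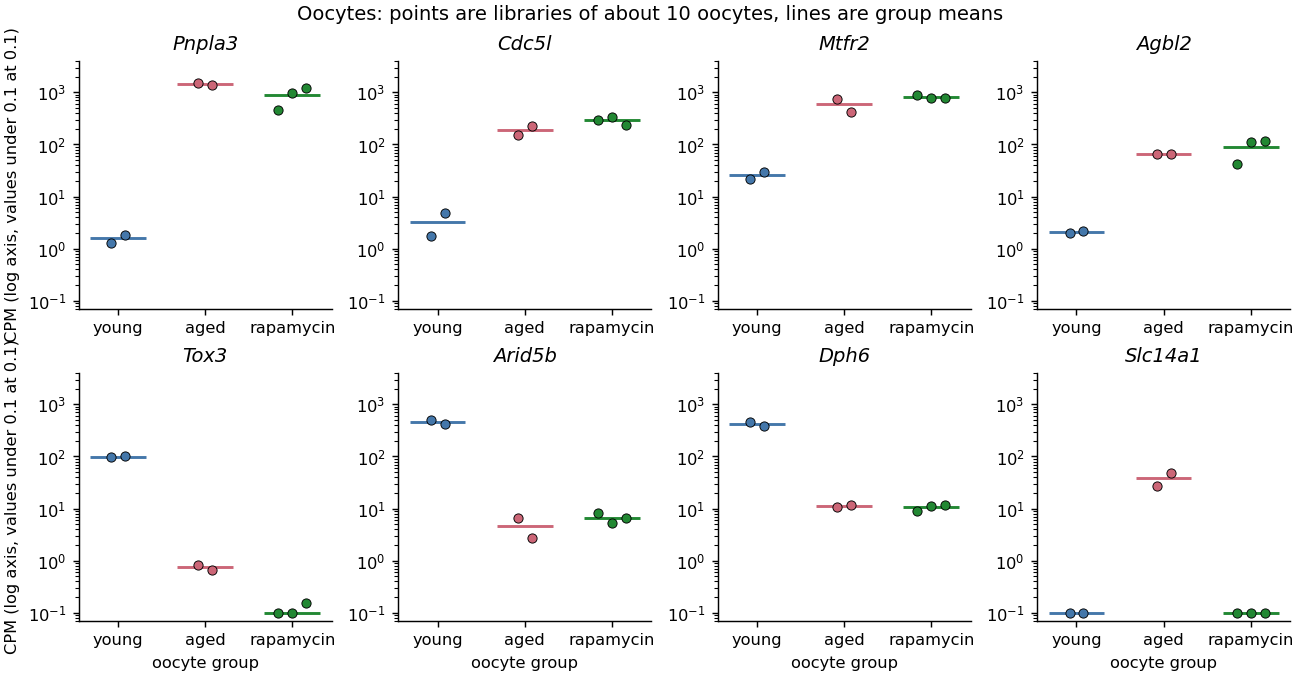
CPM of 8 genes in each oocyte library on a log axis (values under 0.1 drawn at 0.1), points for libraries of about 10 oocytes and lines for group means. Pnpla3, Cdc5l, Mtfr2 and Agbl2 are low in both young libraries, Tox3, Arid5b and Dph6 are high there, and Slc14a1 is above 0 only in the 2 aged libraries.

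The second comparison asked what rapamycin changed in aged oocytes. The matricellular glycoprotein Sparc averaged 0.854 ± 0.0639 CPM in aged (SD, n = 2) and 15.4 ± 2.15 CPM in rapamycin oocytes (SD, n = 3), a log2 fold change of 4.14 ± 0.55 (edgeR adjusted p = 0.522). The urea transporter Slc14a1 was at 27.5 and 49.0 CPM in the aged libraries and at 0 in all young and rapamycin libraries (edgeR adjusted p = 0.522). Gmnn, an inhibitor of DNA replication licensing, averaged 73.5 ± 7.91 CPM in aged and 403 ± 227 CPM in rapamycin oocytes (edgeR adjusted p = 0.730). No gene of 10083 passed in edgeR, with 603 at an unadjusted p under 0.05 (504 expected by chance) and 11 called by DESeq2. Caln1 (2.52 ± 0.53), Mtus2 (2.61 ± 0.56) and Got1 (2.03 ± 0.47) also leaned higher, and Chrdl1 (-2.97 ± 0.57), Fancg (-2.50 ± 0.53), Kcng2 (-4.50 ± 1.08) and Stat3 (-1.32 ± 0.33) lower, none past the threshold in edgeR. Sparc, Gmnn, Caln1, Mtus2, Chrdl1 and Kcng2 were among the 11 called by DESeq2.

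Cytosolic ribosomal proteins were above 0 in 73 of 73 members, with a median log2 fold change of 1.21 (camera adjusted p = 1.55e-19, adjusted p = 0.191 with an estimated correlation). In rapamycin 1 the list stood at 1.27 log2 units and in the other rapamycin libraries at 0.205 and 0.229, against -0.980 and -0.336 in the aged libraries. Nuclear OXPHOS subunits were above 0 in 58 of 70 members (median 0.58, camera adjusted p = 7.1e-07, adjusted p = 0.142 with an estimated correlation). Antioxidant defence genes, among them Hmox1 (2.56 ± 0.67) and the metallothionein Mt1 (4.89 ± 1.34), had a median of 0.53 (camera adjusted p = 0.00362, adjusted p = 0.142 with an estimated correlation). Autophagy and lysosome genes, such as the protease Ctsd (-1.02 ± 0.44) and the glucosidase Gaa (-1.97 ± 0.64), had a median of -0.44 (camera adjusted p = 0.0132, adjusted p = 0.279 with an estimated correlation). That list stood at -0.636 in rapamycin 1 and at -0.035 and 0.066 in the other rapamycin libraries, against 0.419 and 0.232 in the aged ones. It still passed without rapamycin 1 (median -0.42), and lost the call without aged 1 (-0.19) or young 2 (-0.35). Cumulus and granulosa cell markers had a median of 1.26 over 12 members (camera adjusted p = 0.0118, adjusted p = 0.213 with an estimated correlation), and lost the call without rapamycin 1 (median 0.42). Of these, Inha was at 77.2 CPM and Gja1 at 31.5 CPM in rapamycin 1, and at most 4.05 and 2.40 CPM in the other 6 libraries, while the steroidogenic enzyme Cyp11a1 was at 3.92 to 7.26 CPM in the 3 rapamycin libraries. No list member passed over all genes in edgeR or DESeq2, and 1, a cumulus and granulosa marker, passed when adjusted over the list alone. The other 10 lists did not pass with camera (adjusted p from 0.0649 to 0.868). With fry, translation initiation and elongation (adjusted p = 0.0111), antioxidant defence (adjusted p = 0.0111) and nuclear OXPHOS subunits (adjusted p = 0.0309) passed, all 3 higher. Mtor (-1.13 ± 0.63) and Eif4ebp1 (0.54 ± 0.59) did not pass in either tool.

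Without rapamycin 1, edgeR called 6 genes, with Sparc (4.19 ± 0.51), Gmnn (1.91 ± 0.23) and Mtus2 (2.97 ± 0.30) higher and Slc14a1, Kcng2 (-6.42 ± 0.60) and Tktl2 (-4.39 ± 0.45) lower in rapamycin oocytes. Tktl2, a transketolase-like gene, is named outside the rule because it was among these 6. In the same fit Sparc (-2.84), Gmnn (-2.27) and Mtus2 (-3.39) were called lower in aged than in young oocytes. Kcng2 (6.53) and Slc14a1 were called higher there. None of these was called between rapamycin and young oocytes. Both sets of calls rest on the same aged libraries, so they are not independent.

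The third comparison set rapamycin oocytes against young oocytes. Most of the genes that edgeR called between aged and young oocytes in the fit of all libraries were called in the same direction here. Pnpla3 rose by 9.08 ± 0.68 (edgeR adjusted p = 0.00325), Cdc5l by 6.43 ± 0.61 and Mtfr2 by 5.02 ± 0.45 (edgeR adjusted p = 0.00714 for both). Arid5b fell by 6.11 ± 0.48 (edgeR adjusted p = 0.00395) and Dph6 fell by 5.31 ± 0.36 (edgeR adjusted p = 0.0025). Tox3, with 1 count in all rapamycin libraries, was 1700-fold lower, with a counting interval of 304 to 67200. The tissue-specific defensin Defb8 had 0 counts in the rapamycin libraries and was at least 124-fold lower. Rrs1, a ribosome biogenesis factor, rose by 6.34 ± 0.98 and the purine salvage gene Pnp2 by 5.80 ± 0.85. Of the 75-base words of Pnp2, 78.7% occurred in no other gene. Gsto2 was 68.0-fold higher (18.5 to 565), and Sh3rf2 108-fold lower (29.5 to 900.0). Agbl2 rose by 5.42 ± 0.63 and Ddr2 fell by 5.74 ± 0.54. Defb8, Rrs1, Pnp2, Gsto2 and Sh3rf2 were not particular to rapamycin oocytes. In the edgeR fit without rapamycin 1, Rrs1 (5.63), Pnp2 (5.42) and Gsto2 (5.45) were called higher in aged than in young oocytes. Sh3rf2 (-6.43) and Defb8 were called lower there, and none of them was called for rapamycin against aged.

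Of 10083 genes, edgeR called 43, 21 higher and 22 lower, with 898 at an unadjusted p under 0.05 (504 expected by chance). Of the 27 genes called in aged against young oocytes, 25 were among the 43, 15 higher and 10 lower in both. Independent lists would share 0.0333 and 0.024 genes, but both comparisons use the same young libraries. Of the 27 genes of smallest p in each comparison, 21 were shared, against 5.72 on average and at most 10 in simulated unchanged groups set against the same simulated young libraries. Cytosolic ribosomal proteins were above 0 in 58 of 73 members (median 0.78, camera adjusted p = 0.0051, adjusted p = 0.886 with an estimated correlation), with Rps10 at 1.24 ± 0.55 and Rpl10a at 2.33 ± 0.97, neither past the threshold in edgeR or DESeq2. The list stood at 1.27 log2 units in rapamycin 1, at 0.205 and 0.229 in the other rapamycin libraries and at 0.096 and -0.141 in the young ones. Without rapamycin 1 its median was 0.20 and without young 2 it was 0.67, and the camera call ended in both cases. The other 14 lists had camera adjusted p from 0.154 to 0.889. The spindle gene Nusap1 (1.41 ± 0.35), the disulfide isomerase Pdia6 (-3.47 ± 0.73) and Eif4ebp1 (1.87 ± 0.63) did not pass in edgeR, while DESeq2 called Nusap1 and Pdia6. In edgeR 1 heat shock and unfolded protein response member passed when adjusted over the list alone. The count of 43 was 0 without young 1, 2 without young 2, 15 without aged 1 or aged 2, 304 without rapamycin 1, 12 without rapamycin 2 and 8 without rapamycin 3.

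Whether rapamycin oocytes lay back toward young ones was asked by setting the rapamycin effect against the age effect over genes. The correlation across 10083 genes, which are not independent replicates, was -0.536. Simulated unchanged groups sharing the aged libraries gave -0.568 on average (-0.589 to -0.550). The covariance was -0.693, against -0.367 (-0.389 to -0.343) in the simulations. So the correlation was weaker than simulated while the covariance was larger, and the measures point opposite ways. Each simulated gene was drawn independently and no simulated library was made to stand apart, also in the simulations of shared genes. A return toward young can therefore not be read from these values. The aged libraries enter both effects with opposite sign, which by itself gives a negative correlation.

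In hippocampus of offspring, immediate early genes, which neurons transcribe within minutes of activity, were higher after birth to an aged mother than to a young one. Fos rose from 6.09 ± 1.16 CPM (SD, n = 4) to 42.2 ± 17.5 CPM (SD, n = 3), a log2 fold change of 2.79 ± 0.27 (edgeR adjusted p = 0.00576). Fosb rose by 2.04 ± 0.19 (edgeR adjusted p = 0.00576), from 9.68 ± 0.332 to 39.8 ± 11.7 CPM. Egr2 rose by 3.28 ± 0.43, Arc, a regulator of synaptic receptor trafficking, by 1.62 ± 0.21, the kinase Sik1 by 1.48 ± 0.19 and the orphan nuclear receptor Nr4a1 by 1.43 ± 0.18 (edgeR adjusted p = 0.0279 for each). Egr4 rose from 23.7 to 67.0 CPM with the same edgeR adjusted p. Fos lies on chromosome 12 from 85473890 to 85477273 and Arc on chromosome 15 from 74669083 to 74672570 of GRCm38. These 7 were all the genes called of 14877, with 522 at an unadjusted p under 0.05, fewer than the 744 expected by chance. For each of the 7, every library of offspring of aged mothers lay above every library of offspring of young mothers. Genes picked by small p in the same data tend to be so separated, so this adds no support. Over all genes tested, 5.44% had no overlap in either direction, against 5.71% by chance.

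Of 41 immediate early genes, 7 rose, 25 were called higher when adjusted over the list alone and 38 were above 0, with a median of 0.71 (camera adjusted p = 3.1e-81, adjusted p = 0.00332 with an estimated correlation). Inflammation and interferon response genes lay lower, with 28 of 36 below 0, a median of -0.50, none called over all genes in edgeR, 1 (Gbp3) called by DESeq2, and 8 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.08e-08, adjusted p = 0.00608 with an estimated correlation). Among them were the antiviral enzyme Oas1a (-2.21 ± 0.53), the interferon regulator Irf7 (-1.78 ± 0.44), the guanylate-binding protein Gbp3 (-1.40 ± 0.33) and Oasl2 (-0.89 ± 0.24). Levels were low, with Oas1a at 0.603 to 1.115 CPM and Irf7 at 1.36 to 3.99 CPM in offspring of young mothers. Glucocorticoid response genes had 20 of 25 above 0, a median of 0.30, and 8 called when adjusted over the list alone (camera adjusted p = 7.3e-13, adjusted p = 0.0281 with an estimated correlation). Tsc22d3 (1.49 ± 0.22), Pdk4 (1.40 ± 0.23) and Sgk1 (1.11 ± 0.19) led that list without passing over all genes in edgeR, and DESeq2 called all 3. Circadian clock genes had 18 of 22 above 0 and a median of 0.24, with 3 called when adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.00607 with an estimated correlation), led by Per1 (0.67 ± 0.17), Hlf (0.48 ± 0.13) and Nfil3 (0.73 ± 0.21). Thalamus and habenula markers, a neighbouring region, were above 0 in 11 of 15, with a median of 0.19 (camera adjusted p = 0.000266, adjusted p = 0.0267 with an estimated correlation), among them Slc17a6 (1.39 ± 0.44), Zic1 (2.15 ± 0.70) and Tcf7l2 (0.84 ± 0.33). Zic1 stood at 37.0 CPM in aged 1 and at most 10.1 CPM in the other 9 libraries. With an estimated correlation, leaving out young 2 brought the adjusted p to 0.0607 for immediate early genes and circadian clock and 0.0922 for inflammation and interferon response, while over all single libraries left out it ran from 0.0169 to 0.209 for thalamus and habenula and from 0.0176 to 0.128 for glucocorticoid response.

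Another 13 lists passed with camera and lost the call with an estimated correlation, at adjusted p of 0.0835 or more. Cytosolic ribosomal proteins (median 0.28, 75 of 76 above 0, adjusted p = 0.612 with an estimated correlation), nuclear OXPHOS subunits (0.09, adjusted p = 0.694 with an estimated correlation), astrocytes (0.20), oligodendrocytes and myelin (0.23), choroid plexus (0.22), cerebral cortex layers (0.26), meninges and fibroblasts (0.55), antioxidant defence (0.08), heat shock and unfolded protein response (0.03) and mTOR pathway components (0.06) lay higher. When adjusted over the list alone, 1 member was called in each of the cortex, striatum, heat shock and mTOR lists. Endothelium and mural cells (-0.54), glutamatergic synapse and plasticity (-0.11) and GABAergic interneurons (-0.10) lay lower. The endothelial tight junction gene Cldn5 was at -1.05 ± 0.37 and Ly6a at -1.54 ± 0.49, neither past the threshold in edgeR or DESeq2. The other 9 lists, translation, autophagy and lysosome, DNA damage repair, DNA methylation and chromatin, imprinted genes, hippocampal subfields, adult neurogenesis, microglia and striatum, had camera adjusted p from 0.0838 to 0.449. Of the 13 lists, ribosomal proteins, astrocytes, cerebral cortex layers and endothelium kept the camera call without any single library, and the others lost it without at least 1. With fry, 6 lists passed, namely immediate early genes, circadian clock, inflammation and interferon response, glucocorticoid response, mTOR pathway components and thalamus and habenula, at adjusted p from 0.00256 to 0.0466. Red blood cell markers had 2 tested members (median 0.25) and were not tested as a list. Fam210b (-1.05 ± 0.19), Brd9 (-0.84 ± 0.17), Noc2l (-0.60 ± 0.14), Ddit4 (0.59 ± 0.15), Mtor (-0.25 ± 0.22) and Eif4ebp1 (0.30 ± 0.52) did not pass in edgeR, while DESeq2 called Fam210b, Brd9 and Noc2l. The count of 7 was 0 without young 1, 15 without young 2, 2 without young 3, aged 1, aged 3, rapamycin 1 or rapamycin 3, and 50 by DESeq2.

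**Figure D3:**
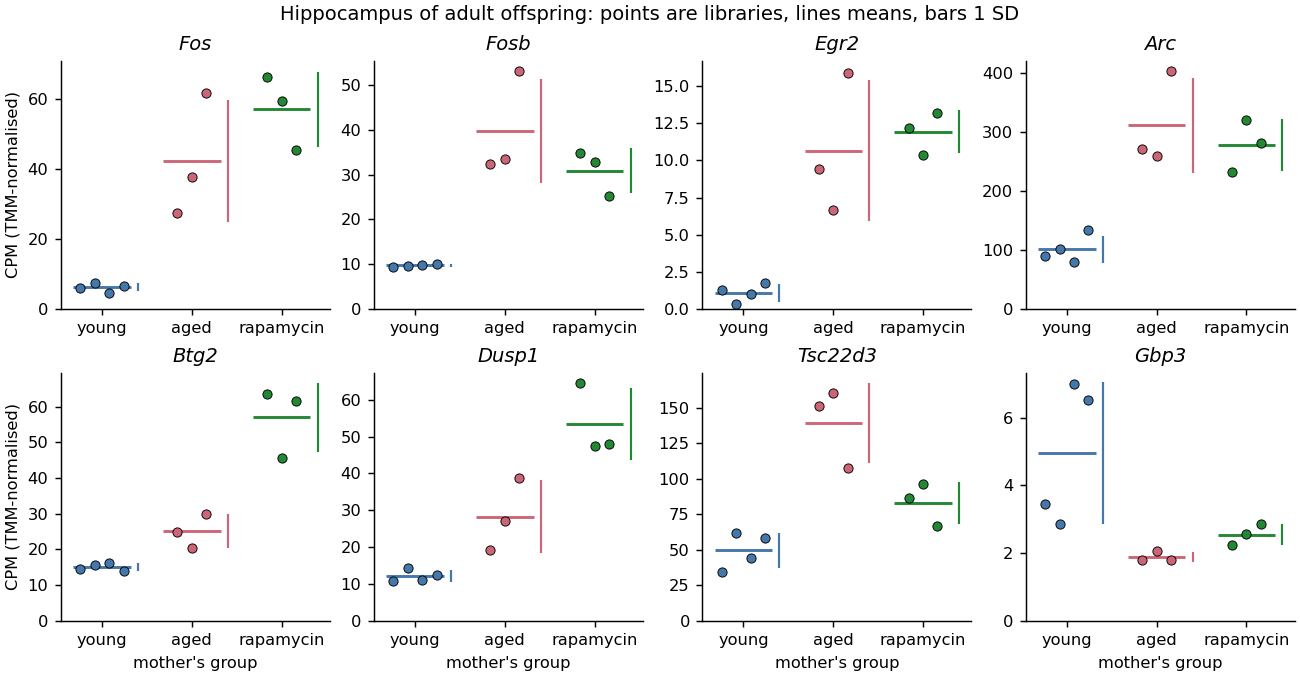
CPM of 8 genes in hippocampus of offspring by the mother's group, points for libraries, horizontal lines for means and vertical bars for 1 SD (n = 4, 3 and 3). Fos, Fosb, Egr2 and Arc are low in all 4 libraries of offspring of young mothers, and Btg2 and Dusp1 are highest in the 3 libraries of offspring of rapamycin-treated mothers.

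Offspring of rapamycin-treated aged mothers were next set against offspring of untreated aged mothers. The antiproliferative gene Btg2, itself an immediate early gene, averaged 25.1 ± 4.82 CPM in offspring of aged mothers and 57.0 ± 9.81 CPM in rapamycin offspring (SD, n = 3 each), a log2 fold change of 1.18 ± 0.18 (edgeR adjusted p = 0.531). The mitochondrial protein gene Fam210b averaged 24.2 ± 3.53 and 57.2 ± 6.02 CPM (1.24 ± 0.20, edgeR adjusted p = 0.531), and Mocs2, an enzyme of molybdenum cofactor synthesis, 68.2 ± 5.76 and 16.3 ± 2.70 CPM (-2.06 ± 0.36, edgeR adjusted p = 0.702). No gene of 14877 passed in edgeR, with 673 at an unadjusted p under 0.05, fewer than the 744 expected by chance, and 11 called by DESeq2. The mRNA decay factor Zfp36 (1.22 ± 0.22) and the oligodendrocyte precursor receptor Gpr17 (0.72 ± 0.16) leaned higher, and Bambi (-1.07 ± 0.22), Hspa1a (-0.69 ± 0.15) and Nppc (-1.21 ± 0.27) lower. DESeq2 called all of these but Gpr17, and also Btg2, Fam210b and Mocs2.

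Immediate early genes split, with 12 above 0 and 29 below (median -0.20, camera adjusted p = 0.218), 5 called higher when adjusted over the list alone, and a fry adjusted p for change in either direction of 0.000376. Klf2 (1.07 ± 0.25), Dusp1 (0.92 ± 0.24) and Ier2 (0.88 ± 0.25) were among those above 0. Glucocorticoid response genes were below 0 in 17 of 25 (median -0.14, camera adjusted p = 0.00158, adjusted p = 0.558 with an estimated correlation), with 3 lower when adjusted over the list alone and Sgk1 (-0.73 ± 0.21), Pdk4 (-1.03 ± 0.25), Cdkn1a (-0.99 ± 0.29) and Tsc22d3 (-0.75 ± 0.24) in front. Endothelium and mural cell markers were above 0 in 24 of 25 (median 0.68, camera adjusted p = 1.16e-07, adjusted p = 0.558 with an estimated correlation), such as Kdr (1.34 ± 0.56) and Vwf (0.87 ± 0.36). Cytosolic ribosomal proteins were below 0 in 75 of 76 (median -0.38, camera adjusted p = 2.92e-13, adjusted p = 0.673 with an estimated correlation) and nuclear OXPHOS subunits in 74 of 75 (-0.30, camera adjusted p = 9.27e-11, adjusted p = 0.673 with an estimated correlation), with Ndufs4 at -0.60 ± 0.30. The ribosomal list stood at -0.911 in rapamycin 1, -0.435 in rapamycin 3 and 0.671 in rapamycin 2. In aged 1, aged 2 and aged 3 it stood at 0.505, 0.383 and 0.015, all below rapamycin 2. Translation (-0.15), heat shock (-0.14), astrocytes (-0.17), choroid plexus (-0.67), antioxidant defence (-0.13) and thalamus and habenula (-0.15) also lay lower, and DNA methylation and chromatin regulators (0.15) and glutamatergic synapse (0.17) higher, all with an adjusted p of at least 0.558 with an estimated correlation. Slc17a6 (-1.56 ± 0.49), Tcf7l2 (-1.06 ± 0.37) and Mtor (0.41 ± 0.23) did not pass in either tool. The camera calls of choroid plexus, glutamatergic synapse, thalamus and habenula, glucocorticoid response, antioxidant defence and astrocytes ended without at least 1 single library. The other 15 lists had camera adjusted p from 0.0521 to 0.964, and no list passed with fry for a shared direction (lowest adjusted p 0.445). With the level of ribosomal proteins as a covariate, chosen after seeing the data, the medians of 5 of these lists changed sign, ribosomal proteins to 0.03, OXPHOS subunits to 0.03, antioxidant defence to 0.10, glutamatergic synapse to -0.02 and astrocytes to 0.06. For ribosomal proteins this follows by construction, because the covariate is that list's own level and takes out its difference. Without young 3, 1 gene was called.

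Against offspring of young mothers, rapamycin offspring again had higher immediate early genes. Fos rose by 3.23 ± 0.28 (edgeR adjusted p = 0.00154), to 57.0 ± 10.6 CPM (SD, n = 3), and Btg2 by 1.92 ± 0.16 (edgeR adjusted p = 0.00154). The phosphatase Dusp1 rose by 2.13 ± 0.23 (edgeR adjusted p = 0.00832), Fosb by 1.67 ± 0.19 (edgeR adjusted p = 0.0115), the matricellular protein Cyr61 by 2.28 ± 0.27 (edgeR adjusted p = 0.0153) and Egr2 by 3.45 ± 0.43 (edgeR adjusted p = 0.0179). Sik1 (1.41 ± 0.19) and Ier2 (1.68 ± 0.23) rose as well. These 8 were all the genes called of 14877, with 540 at an unadjusted p under 0.05, fewer than the 744 expected by chance. Of the 8, 4 were also called in offspring of untreated aged mothers. Independent lists would share 0.00376 genes, but both comparisons use the same young libraries. Of the 7 genes of smallest p in each comparison, 4 were shared, against 0.7 on average and at most 2 in simulated unchanged groups.

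All 8 belonged to the immediate early list, of which 34 of 41 were above 0 and 19 were called when adjusted over the list alone (median 0.37, camera adjusted p = 5.96e-68, adjusted p = 0.0042 with an estimated correlation). Inflammation and interferon response genes lay lower in 28 of 36 (median -0.44, camera adjusted p = 1.01e-08, adjusted p = 0.00896 with an estimated correlation), none called in edgeR or DESeq2. Examples were Isg15 (-1.24 ± 0.42), Ifitm3 (-1.11 ± 0.39) and Irf7 (-1.17 ± 0.43). Isg15 stood at only 0.928 to 2.43 CPM and Irf7 at 1.36 to 3.99 CPM in offspring of young mothers. Leaving out rapamycin 2 brought the adjusted p with an estimated correlation to 0.103 for immediate early genes and 0.150 for inflammation and interferon response, and leaving out rapamycin 3 to 0.0565 for the second. Hippocampal subfields (median -0.19, camera adjusted p = 0.00166, adjusted p = 0.603 with an estimated correlation), with Calb1 (-0.51 ± 0.22) and Rgs14 (-0.49 ± 0.16), and GABAergic interneurons (-0.11, adjusted p = 0.726 with an estimated correlation), with Vip (-0.55 ± 0.18), lost the call. So did nuclear OXPHOS subunits (-0.21), cytosolic ribosomal proteins (-0.10), translation (-0.08), heat shock (-0.10), glucocorticoid response (0.20), circadian clock (0.16) and DNA methylation and chromatin regulators (0.10), at adjusted p of at least 0.0815 with an estimated correlation. Among the 11 lists, immediate early genes, inflammation and interferon response and circadian clock kept the camera call without any single library. The same 3 passed with fry, at adjusted p of 0.00466, 0.0159 and 0.0293. The other 16 lists had camera adjusted p of 0.127 or more. Gpr17 (0.87 ± 0.15), Gbp7 (-1.24 ± 0.29) and Tmem68 (-0.78 ± 0.18) did not pass in edgeR, while DESeq2 called all 3. The count of 8 was 2 without young 1, 4 without young 3, 5 without aged 1 or rapamycin 3, 3 without rapamycin 1, and 31 by DESeq2.

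Over 14877 genes in hippocampus, the rapamycin effect and the age effect correlated at -0.636. Simulated unchanged groups sharing the offspring of aged mothers gave -0.533 (-0.579 to -0.496), and the covariance was -0.091 against -0.061. Each simulated gene was drawn independently, also in the simulations of shared genes. The real libraries shared a first component with 44.3% of the variance that did not separate the groups. The comparison therefore cannot show whether rapamycin offspring lay back toward offspring of young mothers.

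Oocytes and hippocampus were compared over the 9053 genes tested in both. For aged against young, 0 genes were called in both by edgeR, with 0.00365 expected for genes called higher, and DESeq2 also gave 0. For rapamycin against aged, edgeR called 0 genes in either tissue. Fold changes correlated across genes at -0.036 for aged against young, -0.141 for rapamycin against aged and 0.063 for rapamycin against young. Of the 27 genes called in oocytes, 19 were tested in hippocampus, where 8 had the same direction, 1 an unadjusted p under 0.05 and the largest absolute log2 fold change was 0.91.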

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

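The depth and cell-dilution tests of the oocyte library rapamycin 1, the depth test of genes near on or off, and all 3 tests of the immediate early genes were chosen after the result was seen, and 1 of the dilution tests was added because of how the other came out. The bound of the test of neighbouring brain regions was also changed after its result was seen, from the smallest fold change of a called gene, which had excluded that explanation, to the median of all immediate early genes, which leaves it open. The remaining tests, and the counts of other splits, were set beforehand.

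In offspring of young mothers (n = 4), Dixon's test picked out 4 of 87 values, while chance picks out about 1 in 20 groups. They were the level of the autophagy and lysosome list in young 3, at -0.056 log2 units against 0.009 to 0.014 in the others, and of glutamatergic synapse genes in young 2, at -0.333 against 0.091 to 0.169. Astrocyte genes in young 2 stood at 0.480 against -0.369 to -0.230, and Ddit4 in young 2 at 64.0 CPM against 49.7 to 50.9.

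Oocyte rapamycin 1 stood apart from the other 6 libraries, and its highest correlation was still 0.786 after all libraries were thinned to the smallest total, which argues against depth. Against the mean of all other oocyte libraries, genes with the polyadenylation element TTTTA near the 3' end were -0.15 log2 units from genes without it. The 95% interval, which takes genes as independent, was -0.227 to -0.072, and the rearranged motifs gave -0.085 to -0.046. The test set beforehand asked for a rise under tail-dependent capture, and the value is opposite to that. Loss of mRNAs with the element was not tested, so a cause related to the tail stays open. Single genes with it went both ways against the mean of rapamycin 2 and 3. Wee2 (1.33) was higher while Mos (-6.69), H1foo (-4.28) and Gdf9 (-4.12) were lower. Btg4 (0.23), at 6840 CPM, lay within the 5403 to 7129 CPM of the other 6 libraries. For RNA of cumulus or granulosa cells, the test first set compared the median of the oocyte identity list, -1.51 (interquartile range 3.08), with Gdf9 at -4.12, and it came out in favour of dilution. A second test was then added because so wide a spread cannot separate the outcomes, and it found 14 of 52 members higher than in both other rapamycin libraries, which plain dilution would not give. The 2 tests disagree and the raised Inha and Gja1 remain, so cells of the follicle stay a candidate source of part of the difference, and a biological cause within the treated group was not tested.

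Genes near on or off between young and aged oocytes were 34 for the real split, 17 in each direction. Such genes were at least 10 CPM in both libraries of one group and at most 1 CPM in both of the other. Both other splits of the same 4 libraries gave 0. So few splits allow no share under 0.05. Single libraries differed by these bounds in 3 genes between young 1 and young 2, which kept the other splits low. The aged libraries differed in 16, and libraries of different groups in 66 to 83. The splits alone therefore cannot exclude chance differences between pools of about 10 oocytes. Reads shared with near-identical genes are unlikely to be the main cause, with a median of 100% of 75-base words unique over the 27 called genes, though 3 were under 90%. After thinning, 27 of the 27 kept a 4-fold difference in the same direction, and 17 were still called. Genes called for large differences could hardly lose them when totals of at most 8334873 counts were thinned to 3912163. This test therefore says little about depth. Age, the hormone dose and differences of stock between the mice of each age remain open and untested.

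Immediate early genes were higher in hippocampus of offspring of both aged groups. All 7 genes called for aged against young were still called with ribosomal protein level as a covariate. That level ran from -0.545 to 0.702 in offspring of young mothers and from 0.015 to 0.505 in offspring of aged mothers. It did not separate these groups, so the spread it follows is unlikely to be the whole cause. Whether it follows the mix of cell types was not tested, so a difference in cell mix stays open. The highest median of the cortex, thalamus and striatum lists was 0.26 and that of immediate early genes 0.71, but thalamus genes spread widely (interquartile range 0.80), and although for rapamycin against young the lists lay at 0.03 for thalamus, 0.13 for cortex and 0.21 for striatum without passing, against 0.37 for immediate early genes, tissue from neighbouring regions stays open. Circadian clock genes were higher too, with an adjusted p with an estimated correlation of 0.00607 for aged and 0.0815 for rapamycin offspring against young (camera 0.00448), and for glucocorticoid response 0.0281 and 0.603, so time of day or handling before collection may contribute and cannot be told apart from the mother's age. The mother's age itself stays open.

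For hippocampus aged against young, 1 of 35 splits of the 7 libraries, the real one, called as many as 7 genes, and the highest other called 1. This is the smallest share that 35 splits can give, and several such tests were run. The count also fell to 0 without young 1. Chance is thus made less likely for the count but is not excluded. For the lists of aged against young, 2 of 35 splits gave 18, the highest other also 18, and chance cannot be excluded. For rapamycin against young, 4 of 35 splits called 8 or more genes, the highest other 2417 (rapamycin 2, young 2 and young 4 against the rest), which points to a structure of the samples, and 19 of 35 gave 11 or more lists (highest other 14), so chance cannot be excluded for either. For rapamycin against aged, the 10 splits are too few for a share under 0.05, with 10 of 10 at 0 genes (highest other 0) and 4 of 10 at 12 lists (highest other 12).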

How the results depend on the processing

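The covariate for ribosomal protein level and the fit without Rn45s were chosen after the data had been seen, and the other alternatives before. Over 139 gene results and 2116 alternatives, 1773 kept direction and side of the threshold, 275 lost the call, 67 gained one and 1 turned, Eif4ebp1 for hippocampus aged against young at -0.09 with the covariate. Causes were not tested except where fewer libraries or genes entered a fit.

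Oocyte aged against young gave 167 genes without a filter, 17 thinned, 1177 with only the 2 groups, 240 by DESeq2 and 0 to 1168 with a library left out. Rapamycin against aged gave 11 without a filter, 11 by DESeq2 and 0 to 6 with a library left out. Rapamycin against young gave 179 without a filter, 14 with only the 2 groups, 220 by DESeq2 and 0 to 304 with a library left out. Hippocampus aged against young gave 12 with the covariate, 2 with only the 2 groups, 50 by DESeq2 and 0 to 15 with a library left out. Rapamycin against aged gave 2 with only the 2 groups, 11 by DESeq2 and 0 to 1 with a library left out. Rapamycin against young gave 16 with the covariate, 5 with only the 2 groups, 31 by DESeq2 and 2 to 10 with a library left out. Where 1 library of a group was left, it is assumed to vary like the other groups.

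Replicate numbers were not taken to pair the libraries, because not every same-numbered pair correlated over 0.1: the range was -0.092 to 0.004 in oocytes and -0.179 to 0.635 in hippocampus. There, 6 of 9 same-numbered pairs were over 0.1 (median 0.181), against 8 of 24 other pairs (median -0.074), and 4 of 9 hippocampus libraries correlated best with their own number. With a replicate block, the counts were 1, 0 and 0 in oocytes and 9, 0 and 4 in hippocampus, where 6 of the 9 and 3 of the 4 were shared with the fit without a block, and the correlations -0.446 (oocyte age effect against rapamycin effect) and -0.601 (hippocampus age effect against rapamycin effect).

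For the oocyte age effect against rapamycin effect, the correlation was -0.556 without a filter, -0.47 with the stricter filter, -0.521 thinned, -0.524 with only the 2 groups and -0.731 to -0.425 with a library left out. For the hippocampus age effect against rapamycin effect it was -0.537 without a filter, -0.675 with the stricter filter, -0.488 with the covariate and -0.708 to -0.489 with a library left out.

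List medians that turned were, for hippocampus aged against young, OXPHOS (-0.03 without young 3 to 0.357 without young 2, -0.109 with the covariate), meninges (-0.067 without aged 1 to 0.645 without aged 3) and antioxidant defence (-0.03 with the covariate). For rapamycin against aged with the covariate they were ribosomal proteins (0.026), OXPHOS (0.027), antioxidant defence (0.102), glutamatergic synapse (-0.02) and astrocytes (0.055). For rapamycin against young, cytosolic ribosomal proteins came to 0.179 without young 2, 0.169 without rapamycin 1, -0.689 without rapamycin 2 and 0.019 with the covariate. The covariate is the ribosomal list's own level, so the values of ribosomal proteins with it follow by construction.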

Other observations

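The comparisons of this part were chosen after the data had been seen. Of the 17 genes on in young and off in aged oocytes, 7 were at or under 1 CPM in all 3 rapamycin libraries and 0 reached 10 CPM in all 3, counts of CPM with no test. Of the 17 genes off in young and on in aged oocytes, 6 were at 10 CPM or more in all 3 rapamycin libraries and 1, at or under 1 CPM in all 3. Between the young libraries 3 genes were on in one and off in the other, between the aged libraries 16, between rapamycin 2 and rapamycin 3, 22, and between rapamycin 1 and these 215 and 229.

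The polyadenylation element TTTTA also marked a difference between the aged libraries. Each library was set against the mean of all other oocyte libraries, rapamycin 1 among them. In aged 1, genes with the element were 0.19 log2 units higher than genes without it at equal length and GC content of the 3' UTR (95% interval 0.146 to 0.234), above the rearranged motifs at 0.076 to 0.1. In aged 2 the value was 0.026 (-0.005 to 0.058). These intervals take the genes of 1 library as independent, so they do not measure spread between libraries.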
